A study of Mus musculus with 8 samples.

How the data were processed

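RNA was measured by sequencing in 8 mouse libraries: disseminated cancer cells (DCC) from bone marrow cultured without or with interferon-gamma, cells of an early mammary tumour lesion, and the TUBO breast cancer cell line, with 2 biological replicates each per the labels. Total RNA was taken with a column kit (RNeasy Mini) and made into libraries with the Nugen Ovation Mouse RNAseq kit, per the labels' protocols. The dose and duration of the interferon-gamma treatment were not given in the sources used here. The authors deposited 1 table of raw counts per gene symbol for the whole series. TopHat, HTSeq 0.6.1 and the genome build mm10 are named per the submitters' processing notes. The gene annotation, the strand setting and any filter were not given in the sources used here, so reads of overlapping and antisense genes cannot be assigned with certainty, and members of near-identical families (Hspa1a and Hspa1b, Tgtp1 and Tgtp2, several Gbp genes) are uncertain. The table had 23483 lines, of which 23478 name genes and 5 close the table with reads assigned to no gene. Of the gene names 27 read like dates, as spreadsheet programs write them, and 2 were repeats. Coordinates come from GENCODE M21 on GRCm38 (mm10), in which 21871 gene symbols of the table were found.

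The closing lines were kept out of library sizes and tests. Together they held 63.7% and 45.1% of all reads counted in the deposited table in DCC control replicates 1 and 2. These shares were 39.3% and 40.8% in DCC IFN-gamma, 38.9% and 57.2% in early lesion, and 35.2% and 39.7% in TUBO. Reads counted on genes ranged from 15432210 to 30168475 per library, and a floor of 3 counts stood for 0.0953 to 0.183 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Transcripts of the ribosomal precursor gene Rn45s took 2.23% to 4.53% of the gene counts.

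From the deposited counts, CPM values were computed with TMM-normalized library sizes. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust estimation) in 1 model of 4 group means over all 8 libraries, with 4 residual degrees of freedom, after filterByExpr with a minimum count of 10 had left 17069 genes. The common biological coefficient of variation was 0.4158. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and standard errors are the log2 fold change divided by the square root of the F statistic. In all, 4 comparisons were made: DCC IFN-gamma against DCC control, DCC control against early lesion, DCC control against TUBO, and TUBO against early lesion, together with the genes on the same side of both DCC control comparisons. With 2 libraries per group no permutation of the labels could be informative.

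Before the data were examined, 38 gene lists were fixed (26 of cell programmes and 12 of cell type markers, 650 entries). For 7 entries an older symbol was used and 7 were not in the table. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the 38 lists of a comparison, and again with an estimated correlation and with fry. Genes were named by a rule fixed at the same time: per comparison the 6 largest increases and 6 largest decreases among called genes whose libraries did not overlap and whose mean was at least 10 CPM in the higher group, leaving out predicted and clone names. To these the rule adds, for each list described, up to 3 called members in the main direction and 1 in the other, and a fixed panel (among them Erbb2, Ifngr1, Ifngr2, Irf1, Cd274, Cdkn1a, Cdh1, Epcam, Vim, Mki67). For the overlap the rule takes 6 genes per side by the smaller of both changes. Some genes that the rule names are not reported here, and they were also left out of the sensitivity table. Of the others only part are given in the text, with a preference for those whose calls held with 1 library left out. That choice among them was made after their values were seen, as was the choice of any gene said to be.

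The alternatives fixed in advance were RLE and upper quartile factors, no filter, a filter of at least 50 counts in at least 2 libraries, a replicate block, glmTreat against a log2 fold change of 1, DESeq2 1.42.0, a fit of only the 2 groups compared, and leaving out each library in turn. Chosen after seeing the data were a floor of 5 CPM in both libraries of a group, and leaving out DCC control replicate 1 and early lesion replicate 2, the libraries with the most reads outside genes. DESeq2 gave no adjusted p for 7730, 9016, 6873 and 8159 genes in the 4 comparisons. The test was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Of the 2-fold changes it called 44%, 42%, 44% and 41% in the 4 comparisons in the order above. Of the 4-fold changes it called 81%, 93%, 92% and 92%. The runs held 15717, 14887, 14340 and 15530 genes, and 15, 14, 9 and 14 unchanged genes were called. In all 4 comparisons these made up more than a share of 0.05 of the calls. The changed genes were drawn from those with at least 5 CPM in the reference group, so lower ones were not covered. Lists were simulated for interferon-gamma against control only, where camera called 5 of 5 raised and 0 of 5 unchanged ones. The simulated genes were drawn independently and the lists at random, so correlation between genes was not covered. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.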

Results

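RNA-seq counts were analysed for 8 mouse libraries in 4 groups of 2 biological replicates each. Disseminated cancer cells (DCC) had been isolated from the bone marrow of mice with spontaneous metastatic breast cancer and cultured without (DCC control) or with (DCC IFN-gamma) interferon-gamma, the main cytokine of CD4 Th1 cells. The early lesion group held cancer cells from an early mammary tumour lesion whose label names neuT, an activated rat Erbb2 oncogene, and TUBO is a breast cancer cell line. The design text asks how disseminated cells differ from tumours and what a CD4 Th1 response does to their expression. Reads counted on genes totalled 15432210 and 24892318 in DCC control replicates 1 and 2, 27998570 and 28552291 in DCC IFN-gamma, 30168475 and 19812619 in early lesion, and 29318066 and 27122242 in TUBO. The labels give the replicates as separate samples, and each library was counted as such. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom 17.7, 162, 18.6 and 33.6), which argues against 1 library sequenced again but does not show that they are independent. In a principal component analysis of log2 CPM, the first component (61.9% of the variance) parted the 4 DCC libraries from the other 4. On the second (19.3%) DCC control replicate 1 and early lesion replicate 2 stood together, at 129 and 125. The share of reads outside annotated genes was not even across libraries: 49.2% and 31.0% in DCC control, 24.4% and 21.9% in DCC IFN-gamma, 27.4% and 44.1% in early lesion, 19.2% and 18.3% in TUBO. Of 1450 olfactory and vomeronasal receptor genes, a set taken by symbol after the data were seen, 47.7% and 11.9% had a count in DCC control, 2% and 1.17% in DCC IFN-gamma, 1.24% and 63.7% in early lesion and 0.966% in both TUBO libraries.

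The first comparison asked what interferon-gamma changed in cultured DCC. Treated cells carried a broad interferon response. Irf1, a transcription factor of the interferon response, rose from 13.7 ± 4.07 to 941 ± 108 CPM (SD, n = 2), and Igtp, a GTPase of cell-autonomous defence, from 2.63 ± 0.195 to 1265 ± 161 CPM. Genes for cell-autonomous defence, antigen presentation and T cell attraction rose with them, while part of the collagen, osteoblast and mitotic genes fell. In the edgeR test 2148 genes were higher and 1508 lower in treated cells at an adjusted p under 0.05, of 17069 tested.

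Of 20 genes of interferon-gamma signalling and its regulators, 15 rose, none fell and 5 were not called (18 higher when adjusted over the list alone). Its median log2 fold change was 2.53 (camera adjusted p = 5.31e-32, adjusted p = 0.00687 with an estimated correlation). Irf1 (chromosome 11, 53770014 to 53778374 in GRCm38) had a log2 fold change of 6.09 ± 0.25, adjusted p = 7.66e-07 in edgeR. Batf2, a partner of Irf1 in macrophages, changed by 9.86 ± 0.50, adjusted p = 1.28e-05, and Irf7, a regulator of type I interferon genes, by 7.27 ± 0.55, adjusted p = 2.08e-04. Of the receptor genes, Ifngr2 changed by 0.72 ± 0.18, adjusted p = 0.0156, and Ifngr1 was not called (0.30 ± 0.21, adjusted p = 0.327). The Ifngr2 call was lost without DCC control replicate 1 (adjusted p = 0.124), and without that library and early lesion replicate 2 together (0.203). All 20 members of the GBP and IRG families, GTPases that attack intracellular parasites, rose (20 higher when adjusted over the list alone). The median of the list was 7.29 (camera adjusted p = 3.96e-83, adjusted p = 0.00687 with an estimated correlation). Igtp changed by 8.90 ± 0.45, and Iigp1 rose from 1.48 ± 0.408 to 2411 ± 75.0 CPM. Tgtp1 changed by 10.27 ± 0.42, with reads uncertain between near-identical family copies. Of 34 antiviral interferon-stimulated genes 33 rose and 1 was not called (33 higher when adjusted over the list alone). The list had a median of 5.44 (camera adjusted p = 5.29e-52, adjusted p = 0.0758 with an estimated correlation). Zbp1, a sensor of Z-form nucleic acids, changed by 11.55 ± 0.56 and Ifit3 by 8.77 ± 0.61. Among the genes with the largest changes, Apol9b was at least 238-fold higher and Ifi44l at least 173-fold higher, both without a count in the control libraries (floor of 3 counts per library). In DESeq2 Ifi44l was not called (adjusted p = 0.0547). Phf11b was at least 224-fold higher, but its call was lost with any 1 library left out (adjusted p = 0.0994 without DCC control replicate 1, 0.19 without DCC control replicate 2, 0.145 without DCC IFN-gamma replicate 1, 0.275 without DCC IFN-gamma replicate 2).

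Antigen presentation genes rose on both branches. In MHC class I presentation 17 of 19 genes rose and 2 were not called (18 higher when adjusted over the list alone). Over its members the median was 3.19 (camera adjusted p = 1.76e-52, adjusted p = 0.0262 with an estimated correlation). The immunoproteasome subunit Psmb8 rose from 2.35 ± 0.824 to 91.9 ± 9.33 CPM, Psmb9 changed by 4.93 ± 0.42 and the class Ib gene H2-T23 by 5.50 ± 0.40. In MHC class II presentation 8 of 10 rose and 2 were not called (9 higher when adjusted over the list alone). Across the list the median was 4.38 (camera adjusted p = 1.15e-10, adjusted p = 0.144 with an estimated correlation). In the same libraries 12 of 16 macrophage and monocyte markers and 4 of 9 pan-leukocyte genes rose. Cd74, the invariant chain, rose from 1.81 ± 0.712 to 488 ± 33.9 CPM. H2-Aa had no count in the control libraries and 24.9 and 28.5 CPM in the treated ones, at least 177-fold higher. Of 19 genes of T cell chemokines, costimulation and checkpoint ligands 14 rose and 5 were not called (17 higher when adjusted over the list alone). For these genes the median was 4.52, or 4.24 with genes of a group at 0 set to their bound (camera adjusted p = 5.37e-16, adjusted p = 0.101 with an estimated correlation). Cxcl10, a chemokine for Cxcr3-bearing T cells, went from 0.852 and 0.119 CPM to 2635 and 922 CPM (log2 fold change 12.03 ± 1.02, adjusted p = 4.95e-04). Cxcl11 changed by 9.37 ± 0.83, and Cxcl9 by 6.59 ± 0.97, a call lost without DCC IFN-gamma replicate 1 (adjusted p = 0.0851). Cd274 (PD-L1, chromosome 19, 29367455 to 29388095) had 43.5 and 13.4 CPM in the control and 603 and 426 CPM in the treated libraries, but was not called in edgeR (4.19 ± 1.28, adjusted p = 0.0762). It was called in DESeq2 (adjusted p = 0.00649), with the stricter filter on low counts (0.0311), in a fit of the 2 groups alone (0.00416), and without DCC control replicate 1 and early lesion replicate 2 (0.041). It was also called with no filter, where its adjusted p (3.32e-73) is doubtful and may be far too small.

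Inflammatory, cell death, immediate-early and heat shock genes also rose. Of 17 NF-kB and inflammatory cytokine genes 10 rose and 7 were not called (10 higher when adjusted over the list alone). Its median log2 fold change was 1.62 (camera adjusted p = 2.26e-08, adjusted p = 0.0758 with an estimated correlation). Tnfaip3, an inhibitor of NF-kB, changed by 4.74 ± 0.24, and the cytokine Lif by 4.75 ± 0.42. In the list of apoptosis, necroptosis and pyroptosis 13 of 21 rose and 8 were not called (15 higher when adjusted over the list alone). The median of the list was 1.53 (camera adjusted p = 2.32e-10, adjusted p = 0.0276 with an estimated correlation). Mlkl, the executor of necroptosis, rose from 1.42 ± 0.322 to 83.7 ± 25.9 CPM, and Casp1, which cleaves pro-interleukin-1 beta, changed by 3.64 ± 0.57. Of 15 immediate-early and heat shock genes 13 rose and 2 were not called (14 higher when adjusted over the list alone). The list had a median of 2.46 (camera adjusted p = 5.79e-14, adjusted p = 0.148 with an estimated correlation). Hspa1b, an inducible Hsp70, rose from 5.37 ± 1.31 to 927 ± 373 CPM, with reads uncertain between it and its near-identical neighbour Hspa1a. Of 15 unfolded protein and integrated stress response genes 3 rose, 5 fell and 7 were not called (3 higher and 6 lower when adjusted over the list alone). Over its members the median was -0.08 (camera adjusted p = 0.273, adjusted p = 0.645 with an estimated correlation). Of 15 p53 targets 8 rose, 1 fell and 6 were not called (10 higher and 1 lower when adjusted over the list alone). Across the list the median was 1.01 (camera adjusted p = 5.28e-04, adjusted p = 0.148 with an estimated correlation). Mdm2, the ubiquitin ligase of p53, changed by 1.99 ± 0.20, adjusted p = 1.11e-04, Ccng1 by 1.39 ± 0.20 and Cdkn1a (p21, chromosome 17, 29090976 to 29100727) by 1.01 ± 0.14, adjusted p = 8.16e-04. Sesn2 fell by 0.70 on the log2 scale, a call lost without DCC control replicate 1 (adjusted p = 0.191) and without that library and early lesion replicate 2 together (0.282).

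Part of the cell cycle genes changed. Of 24 genes of G1/S and DNA replication 14 rose, 1 fell and 9 were not called (15 higher and 1 lower when adjusted over the list alone). For these genes the median was 0.86 (camera adjusted p = 3.13e-06, adjusted p = 0.148 with an estimated correlation). The licensing factors Cdt1 and Mcm6 changed by 2.14 ± 0.22 and 1.94 ± 0.23. Of 23 genes of G2/M and mitosis 12 fell, none rose and 11 were not called (16 lower when adjusted over the list alone). Its median log2 fold change was -0.91 (camera adjusted p = 1.25e-04, adjusted p = 0.645 with an estimated correlation). Birc5 (survivin) changed by -1.44 ± 0.26, adjusted p = 0.00316, Kif20a by -1.52 ± 0.34, adjusted p = 0.0172 and the proliferation marker Mki67 was not called (-1.06 ± 0.34, adjusted p = 0.0592), although it was with upper quartile factors (adjusted p = 0.0244), with the stricter filter (0.0458), with the floor of 5 CPM (0.0418), in a fit of the 2 groups alone (0.0458), in DESeq2 (0.00264) and without DCC IFN-gamma replicate 2 (0.00708). With no filter its adjusted p was 8.06e-06, which may be too small. The Kif20a call was lost without DCC control replicate 1 (adjusted p = 0.0683) and without DCC control replicate 2 (0.118). Without DCC control replicate 1 and early lesion replicate 2 together the calls of Kif20a (0.0758) and Birc5 (0.0682) were lost. Fry, which does not compare a list with other genes, gave the G2/M list an adjusted p of 0.0667. Vim, a mesenchymal filament, changed by 1.37 ± 0.23, adjusted p = 0.00215, and Erbb2 by 0.73 ± 0.14, adjusted p = 0.00507. The Erbb2 call was lost without DCC control replicate 1 (adjusted p = 0.0586), and both calls without that library and early lesion replicate 2 (Vim 0.087, Erbb2 0.118).

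Part of the matrix and bone genes were lower after treatment. In the same libraries 12 of 16 macrophage and monocyte markers rose. A change in the mix of cells cannot be told apart here from a change within cells. Of 18 fibrillar collagen and matrix genes 7 fell and 11 were not called (7 lower when adjusted over the list alone). The median of the list was -1.44 (camera adjusted p = 7.18e-05, adjusted p = 0.411 with an estimated correlation). Tenascin C (Tnc) dropped from 3247 and 3354 CPM in the control libraries to 107 and 176 CPM in the treated ones, and periostin (Postn) changed by -5.73 ± 0.49. Of 10 osteoblast and cartilage markers 4 fell and 6 were not called (5 lower when adjusted over the list alone). The list had a median of -2.88 (camera adjusted p = 3.33e-05, adjusted p = 0.16 with an estimated correlation). Ibsp, bone sialoprotein, went from 522 ± 157 to 5.82 ± 2.09 CPM, and Alpl, the phosphatase of mineralising cells, from 1429 ± 66.6 to 61.5 ± 25.5 CPM. In the fibroblast and stromal cell list 5 of 13 fell, 2 rose and 6 were not called (6 lower and 2 higher when adjusted over the list alone), and the list was not called (camera adjusted p = 0.0813). There Col1a1 changed by -3.13 ± 0.37 and Pdgfra by 1.84 ± 0.29. Mrvi1 had 1 count over both treated libraries and 19.8 and 23.2 CPM in the control libraries, a ratio of 1122 (95% counting interval 201 to 44347). Hpgd, which degrades prostaglandins, changed by -7.21 ± 1.02 and Gdf10 by -6.93 ± 1.01. The Hpgd call was lost without DCC control replicate 2 and without DCC IFN-gamma replicate 2. That of Gdf10 was lost without either DCC IFN-gamma replicate. Such a fit leaves 1 library in a group and has less power, so these losses do not show that 1 library made the call.

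Markers of macrophages moved with the treatment. Of 16 macrophage and monocyte markers 12 rose and 4 were not called (13 higher when adjusted over the list alone). Over its members the median was 3.17 (camera adjusted p = 4.92e-15, adjusted p = 0.0853 with an estimated correlation). Fcgr1 changed by 4.68 ± 0.42, adjusted p = 9.14e-05 and Aif1 by 6.30 ± 1.54, adjusted p = 0.0333, and the complement gene C1qa went from 8.95 and 12.5 to 238 and 168 CPM (adjusted p = 0.00592). The Aif1 call was lost with any 1 of the 4 libraries left out (adjusted p = 0.145 without DCC control replicate 1, 0.285 without DCC control replicate 2, 0.192 without DCC IFN-gamma replicate 1, 0.159 without DCC IFN-gamma replicate 2), and so was that of C1qa (0.0788 without DCC control replicate 1, 0.141 without DCC control replicate 2, 0.0896 without DCC IFN-gamma replicate 1, 0.0591 without DCC IFN-gamma replicate 2), which DESeq2 did not call (0.0754). Of 9 pan-leukocyte genes 4 rose and 5 were not called (8 higher when adjusted over the list alone). Across the list the median was 2.83 (camera adjusted p = 2.02e-07, adjusted p = 0.187 with an estimated correlation), among them Cd52 (5.98 ± 0.65) and Srgn (3.70 ± 0.24). No marker of T and NK cells (6 tested), B and plasma cells (3), neutrophils and mast cells (7), or erythroid cells and megakaryocytes (7) was called.

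Epithelial genes were near the floor in both DCC groups. Of 22 genes of epithelial adhesion and identity 12 were called lower after treatment, 1 higher (St14, 2.29 ± 0.26) and 9 were not called (15 lower and 1 higher when adjusted over the list alone). For these genes the median was -4.14, or -2.47 with genes of a group at 0 set to their bound (camera adjusted p = 3.37e-06, adjusted p = 0.0758 with an estimated correlation). None of the 12 was above 1.97 CPM on average in DCC control. Grhl2, an epithelial transcription factor, had 1.64 and 1.27 CPM there and no count after treatment, at least 12.4-fold lower. Counts on 1450 olfactory and vomeronasal receptor genes, genes known mainly from sensory neurons, moved the same way: 47.7% and 11.9% of them had a count in DCC control replicates 1 and 2, against 2.0% and 1.17% in the treated libraries.

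All gene counts of this comparison come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 17069 genes, and 1251 of the genes called higher and 1040 of those called lower differed by at least 2-fold. Of the genes called lower, 299 (19.8%) were under 5 CPM in both groups, and olfactory and vomeronasal receptor genes had a count more often in DCC control (47.7% and 11.9%) than in DCC IFN-gamma (2% and 1.17%). Of the 17 lists called by camera, 4 held with an estimated correlation: interferon-gamma signalling, the GBP and IRG GTPases, MHC class I presentation, and apoptosis, necroptosis and pyroptosis. The median log2 fold change of all tested genes was -0.20. With upper quartile factors it was -0.40 and the balance turned, to 1526 genes higher and 2221 lower (40.7% of calls higher, against 58.8%). Without DCC control replicate 1 there were 1193 genes higher and 827 lower, without DCC control replicate 2 1011 lower, and without DCC control replicate 1 and early lesion replicate 2, the libraries with the most reads outside genes, 1017 and 637. DESeq2 called 2272 genes lower, and glmTreat, which tests for a change of more than 2-fold, called 570 higher and 327 lower.

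**Figure D1:**
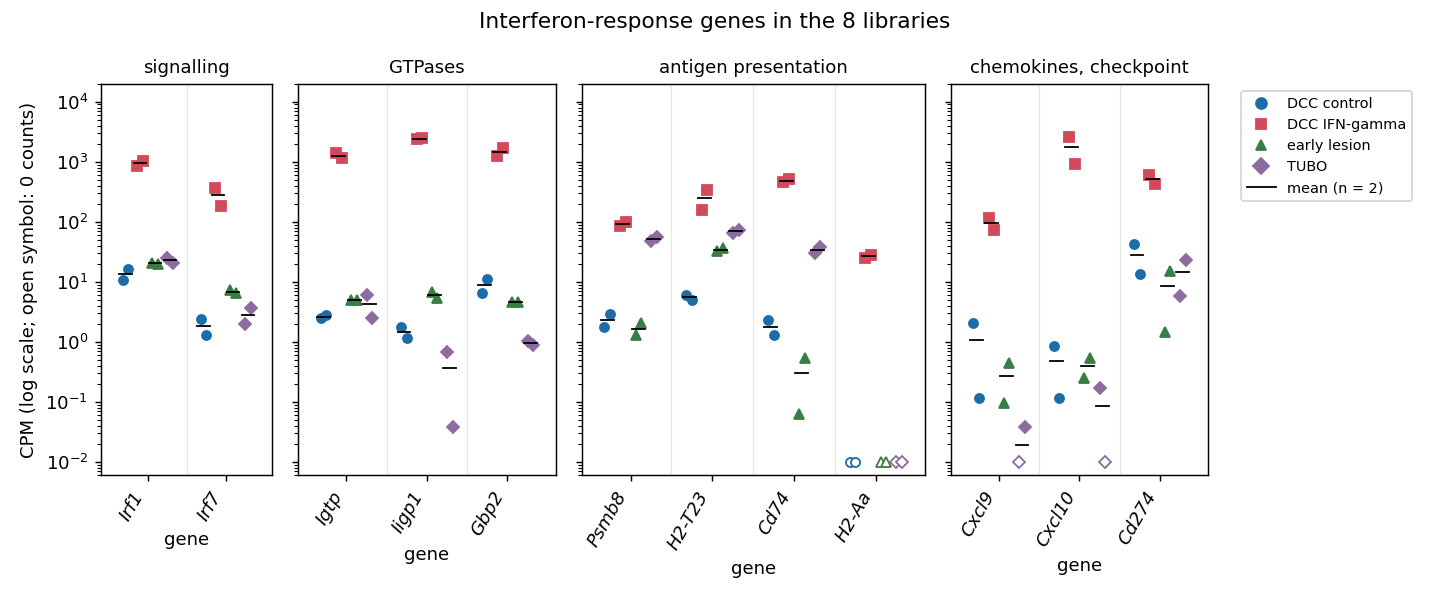
Expression of 12 interferon-response genes in the 8 libraries, in CPM on a log scale, with 1 point per library, a bar at the mean of the 2 replicates, and open symbols at the lower edge for libraries with 0 counts. The 2 DCC IFN-gamma libraries lie above the 2 DCC control libraries for every gene shown, for example at 865 and 1018 CPM against 10.8 and 16.6 CPM for Irf1.

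The second comparison set untreated DCC against cells of the early lesion, a primary tumour site. The 2 sources differed in their cell identity genes. DCC had almost no epithelial transcripts, with Epcam (epithelial adhesion molecule, chromosome 17, 87635979 to 87651129) at 0.0790 ± 0.112 CPM against 815 ± 29.6 CPM in the early lesion and Cdh1 (E-cadherin, chromosome 8, 106603351 to 106670246) at 0.352 ± 0.105 against 503 ± 25.4 CPM. They carried instead high levels of matrix and bone transcripts, with Col1a1 (type I collagen, chromosome 11, 94936224 to 94953042) at 4087 ± 265 CPM against 5.06 ± 0.0860. Proliferation and cholesterol synthesis genes were lower in DCC. In edgeR 3253 genes were higher and 3188 lower in DCC control, 2322 and 2258 of them by at least 2-fold.

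Of 22 genes of epithelial adhesion and identity 21 were lower in DCC control and 1 was not called (22 lower when adjusted over the list alone). Its median log2 fold change was -7.63 (camera adjusted p = 8.80e-45, adjusted p = 0.108 with an estimated correlation). Epcam changed by -12.99 ± 0.41, adjusted p = 3.64e-08, the keratin Krt18 by -12.44 ± 0.49 and Cdh1 by -10.52 ± 0.29, adjusted p = 1.01e-08. In the luminal mammary and ERBB signalling list 12 of 20 were lower, 2 higher and 6 not called (12 lower and 2 higher when adjusted over the list alone). The median of the list was -3.29 (camera adjusted p = 3.16e-08, adjusted p = 0.108 with an estimated correlation). Erbb2 (chromosome 11, 98412470 to 98437716) stood at 22.3 ± 1.44 CPM in DCC control and 242 ± 4.44 CPM in the early lesion (-3.44 ± 0.15, adjusted p = 8.86e-08). Whether reads of a rat neuT transgene were counted on mouse Erbb2 is not known here. Erbb3, the partner receptor, changed by -7.97 ± 0.21 and the luminal factor Tfap2c by -10.10 ± 0.69, whereas the ligand gene Ereg was higher (7.50 ± 0.88). Of 12 milk protein and secretory genes 6 were lower and 6 not called (6 lower when adjusted over the list alone). The list had a median of -2.62 (camera adjusted p = 0.00685, adjusted p = 0.356 with an estimated correlation). The casein gene Csn3 had 14472 and 10828 CPM in the early lesion against 1.22 and 0.0790 CPM. Wfdc18 (at least 5644-fold lower), Rbp7 (at least 445-fold lower), Cytl1 (at least 414-fold lower) and Ceacam10 (at least 315-fold lower) had no count in DCC control.

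Mesenchymal, matrix and bone genes made up the other side. Of 19 mesenchymal and EMT genes 18 were higher in DCC control and 1 was not called (18 higher when adjusted over the list alone). Over its members the median was 6.02 (camera adjusted p = 5.37e-20, adjusted p = 0.118 with an estimated correlation). Sparc changed by 12.61 ± 0.60, the transcription factor Snai2 by 9.92 ± 0.78 and Vim by 4.19 ± 0.26, adjusted p = 7.67e-07. Of 18 fibrillar collagen and matrix genes 14 were higher, 1 lower (Col4a1, -1.73 ± 0.25) and 3 not called (15 higher and 1 lower when adjusted over the list alone). Across the list the median was 9.20 (camera adjusted p = 3.54e-06, adjusted p = 0.379 with an estimated correlation). Biglycan (Bgn) stood at 5515 ± 25.1 against 0.681 ± 0.424 CPM. Among markers of other cell types, 8 of 10 osteoblast and cartilage markers were higher and 2 not called (8 higher when adjusted over the list alone). For these genes the median was 6.21, or 5.46 with genes of a group at 0 set to their bound (camera adjusted p = 2.69e-05, adjusted p = 0.356 with an estimated correlation). Sp7 (osterix), the transcription factor of osteoblasts, had 190.2 and 208 CPM in DCC control and 0 and 0.714 CPM in the early lesion, and Ibsp had 2 counts over the early lesion libraries, a ratio of 14685 (95% counting interval 4065 to 121267). Of 13 fibroblast and stromal cell markers 9 were higher and 4 not called (9 higher when adjusted over the list alone). Its median log2 fold change was 6.49 (camera adjusted p = 1.18e-05, adjusted p = 0.379 with an estimated correlation), with Col1a1 at 9.66 ± 0.50, adjusted p = 1.38e-06. The collagen and fibroblast lists share Col1a1, Col1a2 and Col3a1 (12.67 ± 0.96). Of 16 macrophage and monocyte markers 11 were higher, 1 lower (Cd14, -3.03 ± 0.25) and 4 not called (11 higher and 1 lower when adjusted over the list alone). The median of the list was 4.05, or 3.96 with genes at their bound (camera adjusted p = 1.18e-05, adjusted p = 0.356 with an estimated correlation). C1qb had 13.4 and 14.5 CPM in DCC control and 1 count over the early lesion libraries, a ratio of 759 (95% counting interval 136 to 30026). The opioid peptide gene Penk was at least 2488-fold higher, the collagen-binding proteoglycan gene Fmod changed by 13.97 ± 1.02, the collagenase gene Mmp13 by 13.16 ± 1.03, and Rasl11a was at least 323-fold higher.

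Proliferation and metabolism also differed. All 23 genes of G2/M and mitosis were lower in DCC control (23 when adjusted over the list alone). The list had a median of -2.70 (camera adjusted p = 3.81e-15, adjusted p = 0.356 with an estimated correlation). Mki67 stood at 261 ± 72.7 CPM against 2443 ± 435 CPM (-3.22 ± 0.36, adjusted p = 1.72e-04), and Ccnb1, the mitotic cyclin, changed by -3.15 ± 0.27. Of 24 genes of G1/S and DNA replication 23 were lower and 1 not called (23 lower when adjusted over the list alone). Over its members the median was -2.58 (camera adjusted p = 6.14e-15, adjusted p = 0.108 with an estimated correlation), for example Mcm5 (-4.02 ± 0.27) and Rrm2 (-3.67 ± 0.19). Cdkn1a was higher in DCC control (1.52 ± 0.15, adjusted p = 1.83e-05). All 18 cholesterol synthesis genes were lower (18 when adjusted over the list alone). Across the list the median was -2.46 (camera adjusted p = 5.82e-10, adjusted p = 0.356 with an estimated correlation), with Dhcr7 at -4.05 ± 0.17, adjusted p = 6.34e-08 and Sqle at -3.45 ± 0.28. Of 15 genes of the unfolded protein and integrated stress response 9 were higher, 2 lower and 4 not called (9 higher and 3 lower when adjusted over the list alone). For these genes the median was 1.90 (camera adjusted p = 3.16e-08, adjusted p = 0.108 with an estimated correlation). Ddit3 (CHOP) changed by 5.40 ± 0.20 and Chac1 by 6.04 ± 0.33. Ptgs2, the inducible cyclooxygenase, stood at 997 ± 69.6 against 1.91 ± 0.453 CPM.

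None of the 12 lists that camera called in this comparison held with an estimated correlation. DCC control replicate 1 and early lesion replicate 2 had the most reads outside genes (49.2% and 44.1%) and the most olfactory and vomeronasal receptor genes with a count (47.7% and 63.7%), 1 in each group. Without both libraries 2054 genes were higher and 2058 lower, and glmTreat called 1486 and 1594.

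**Figure D2:**
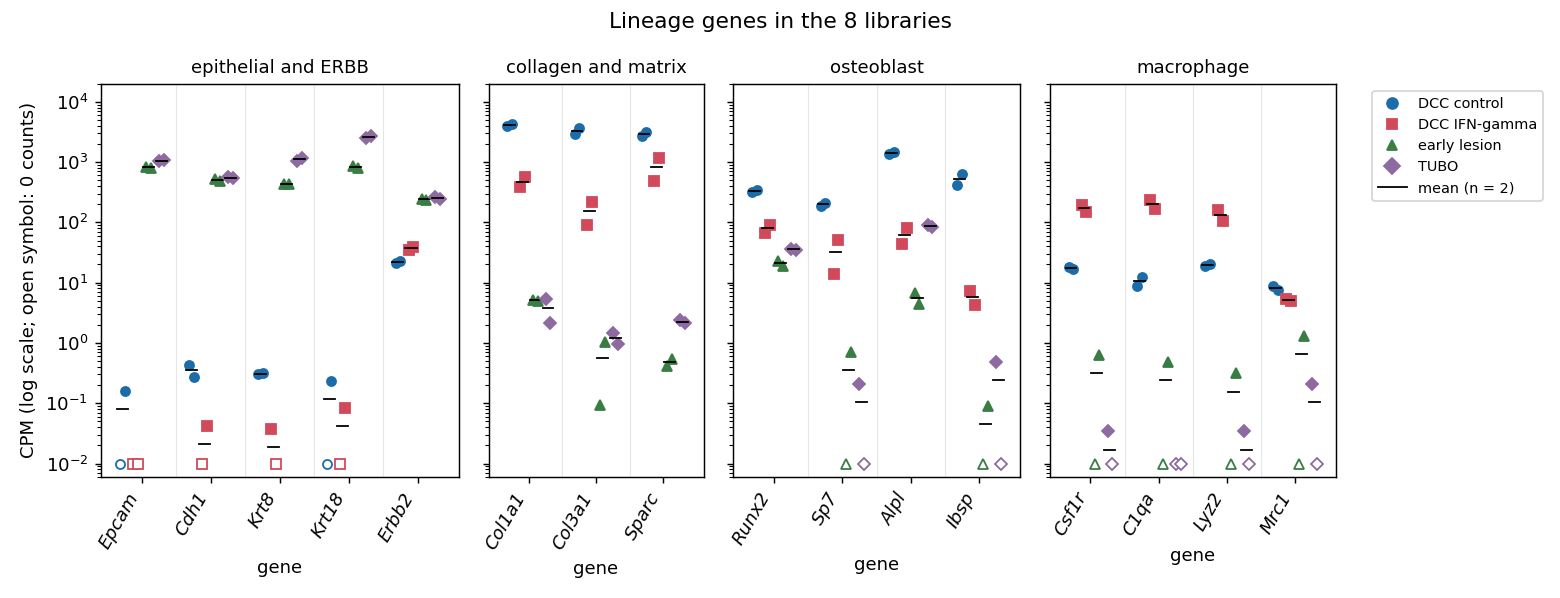
Expression of 16 lineage genes in the 8 libraries, in CPM on a log scale, with 1 point per library, a bar at the mean of the 2 replicates, and open symbols at the lower edge for libraries with 0 counts. Epcam, Cdh1, Krt8 and Krt18 are near the floor in the 4 DCC libraries, the osteoblast and collagen genes drawn (Runx2, Sp7, Alpl, Ibsp, Col1a1 and Col3a1) are highest in DCC control, and Csf1r, C1qa and Lyz2 are highest in DCC IFN-gamma.

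The third comparison set untreated DCC against the TUBO line. The picture for identity genes was close to that against the early lesion. Epcam stood at 1062 ± 39.2 CPM in TUBO, Krt18 at 2602 ± 130.2 CPM and Erbb2 at 252 ± 9.34 CPM, against 0.0790 ± 0.112, 0.119 ± 0.168 and 22.3 ± 1.44 CPM in DCC control. Mesenchymal, collagen and bone genes were higher in DCC control, while glycolysis and hypoxia genes were lower. In edgeR 3776 genes were higher and 3396 lower in DCC control, 2892 and 2309 of them by at least 2-fold, and the median log2 fold change of all tested genes was 0.37 (0.48 with upper quartile factors).

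Of 22 epithelial adhesion and identity genes 21 were lower in DCC control and 1 was not called (21 lower when adjusted over the list alone). Its median log2 fold change was -7.82 (camera adjusted p = 9.05e-46, adjusted p = 0.105 with an estimated correlation). Krt18 changed by -14.11 ± 0.51, adjusted p = 3.35e-08, Epcam by -13.37 ± 0.41, adjusted p = 2.83e-08 and Cdh1 by -10.65 ± 0.29. In the luminal mammary and ERBB list 13 of 20 were lower, 3 higher and 4 not called (14 lower and 3 higher when adjusted over the list alone). The median of the list was -3.22 (camera adjusted p = 5.50e-08, adjusted p = 0.205 with an estimated correlation). Erbb2 changed by -3.50 ± 0.15, adjusted p = 6.68e-08 and Erbb3 by -8.24 ± 0.21, whereas Esr1, the oestrogen receptor, had no count in TUBO and was at least 94.6-fold higher in DCC control (11.5 and 9.11 CPM). Of 19 mesenchymal and EMT genes 18 were higher and 1 not called (18 higher when adjusted over the list alone). The list had a median of 9.14, or 8.76 with genes at their bound (camera adjusted p = 1.68e-19, adjusted p = 0.205 with an estimated correlation). Zeb1, a repressor of epithelial genes, had 1 count over both TUBO libraries and 154 and 173 CPM in DCC control, a ratio of 9118 (95% counting interval 1636 to 360200). Of 18 fibrillar collagen and matrix genes 15 were higher, 1 lower (Col4a1, -1.45 ± 0.25) and 2 not called (15 higher and 1 lower when adjusted over the list alone). Over its members the median was 10.33, or 9.88 with genes at their bound (camera adjusted p = 2.91e-05, adjusted p = 0.574 with an estimated correlation). Fbn1 (fibrillin) was at least 1253-fold higher and Col6a1 changed by 11.97 ± 1.22.

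Fibroblast, osteoblast and macrophage markers were among those higher in DCC control. Of 13 fibroblast and stromal cell markers 12 were higher and 1 not called (12 higher when adjusted over the list alone). Across the list the median was 10.82, or 8.59 with genes at their bound (camera adjusted p = 5.60e-06, adjusted p = 0.564 with an estimated correlation), with Lum at least 246-fold higher. Of 10 osteoblast and cartilage markers 8 were higher and 2 not called (9 higher when adjusted over the list alone). For these genes the median was 6.11, or 4.13 with genes at their bound (camera adjusted p = 0.00151, adjusted p = 0.564 with an estimated correlation), with Sp7 at 10.78 ± 1.32 and Ibsp at 10.99 ± 0.82. Of 16 macrophage and monocyte markers 12 were higher, 1 lower (Cd14, -2.94 ± 0.25) and 3 not called (12 higher and 1 lower when adjusted over the list alone, median 7.86, or 5.25 with genes at their bound, camera adjusted p = 2.91e-05, adjusted p = 0.564 with an estimated correlation). Laptm5 was at least 141-fold higher. GBP and IRG GTPases were higher in untreated DCC too, with 10 of 20 higher, 1 lower and 9 not called (13 higher and 1 lower when adjusted over the list alone, median 2.77, camera adjusted p = 9.50e-04, adjusted p = 0.564 with an estimated correlation). Gbp9 changed by 6.61 ± 0.54 and Gbp8 was at least 51.4-fold higher, with reads uncertain between GBP family members.

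Metabolic and replication genes were lower in DCC control. In glycolysis and hypoxia 13 of 17 were lower, 1 higher (Ndrg1, 1.01 ± 0.25, not called without TUBO replicate 2, adjusted p = 0.0627) and 3 not called (14 lower and 2 higher when adjusted over the list alone, median -1.58, camera adjusted p = 1.94e-04, adjusted p = 0.574 with an estimated correlation). Egln3, an oxygen sensor, stood at 3.82 ± 1.31 CPM against 765 ± 64.4 CPM in TUBO, and Car9, a hypoxia-induced carbonic anhydrase, changed by -5.70 ± 0.75. Of 18 cholesterol synthesis genes 12 were lower and 6 not called (13 lower when adjusted over the list alone, median -1.40, camera adjusted p = 0.00109, adjusted p = 0.584 with an estimated correlation), with Dhcr7 at -3.33 ± 0.17. Of 23 oxidative phosphorylation genes 16 were lower, 1 higher and 6 not called (17 lower and 1 higher when adjusted over the list alone, median -0.70, camera adjusted p = 0.00247, adjusted p = 0.587 with an estimated correlation), with the complex I gene Ndufb8 at -1.95 ± 0.18. Of 24 G1/S and DNA replication genes 14 were lower, 1 higher and 9 not called (15 lower and 1 higher when adjusted over the list alone, median -0.81, camera adjusted p = 0.00708, adjusted p = 0.564 with an estimated correlation), with Mcm5 at -1.96 ± 0.25. Mki67 was not called (-0.40 ± 0.33, adjusted p = 0.347), and neither was the G2/M and mitosis list, with 9 of 23 lower and 14 not called (9 lower when adjusted over the list alone, camera adjusted p = 0.0616). Genes at 0 in TUBO with the largest changes were Rcn3 (at least 2415-fold higher in DCC control), Clip3 (at least 2138-fold), Tpm2 (at least 1603-fold), Ptprg (at least 1599-fold), Kctd12 (at least 1596-fold) and Slit2 (at least 1440.1-fold). None of the 12 lists called by camera held with an estimated correlation. Of the genes called higher, 693 (18.4%) were under 5 CPM in both groups, and glmTreat called 1990 higher and 1544 lower. With the floor of 5 CPM the balance turned, to 3159 higher and 3432 lower (47.9% of calls higher, against 52.6%). The share of olfactory and vomeronasal receptor genes with a count also differed (47.7% and 11.9% in DCC control, 0.966% in both TUBO libraries).

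Both comparisons of untreated DCC were then combined. In DCC control 2267 genes were higher than in both early lesion and TUBO and 2326 lower than in both, while 195 were called on opposite sides. The genes with the largest smaller change were Fmod, Rasl11a, Fabp4, Gpx7, Rcn3 and Col6a1 on the higher side and Wfdc18, Rbp7, Cytl1, Ceacam10, Epcam and Sox10 on the lower side. Where a group had no count, the fitted change that ranks a gene is not a measured size. This holds for Rasl11a in the early lesion and for Wfdc18, Rbp7, Cytl1 and Ceacam10 in DCC control. Sox10, a transcription factor, had 0 and 0.198 CPM in DCC control, 857 and 823 CPM in the early lesion and 1164 and 1234 CPM in TUBO. Of the fixed lists, 20 of 22 epithelial genes were lower than in both, and 18 of 19 mesenchymal genes, 14 of 18 collagen and matrix genes, 8 of 10 osteoblast markers and 11 of 16 macrophage markers were higher than in both. Independent lists of these sizes would share 719.6 genes on the higher side and 634.3 on the lower side. The 2 comparisons use the same DCC control libraries: in 20 simulations of unchanged groups against them the overlap was 0.05 genes on average and 1 at most. No gene was changed in these simulations, so they do not show how much shared controls add where many genes are called. A split of the controls would leave 1 library on each side and was not made, so part of the excess may come from the shared controls. With glmTreat 2250 genes lay on the same side of both.

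The last comparison set the TUBO line against the early lesion, the 2 sources with epithelial expression. Erbb2 stood at 252 ± 9.34 CPM in TUBO and 242 ± 4.44 CPM in the early lesion (log2 fold change 0.06 ± 0.14, adjusted p = 0.777), and neither it nor Epcam (0.38 ± 0.21, adjusted p = 0.226) or Cdh1 (0.13 ± 0.17, adjusted p = 0.578) was called (Epcam was called by DESeq2, adjusted p = 0.03, and in a fit of the 2 groups alone, 0.0344). TUBO had lower levels of proliferation and cholesterol synthesis genes and higher levels of glycolysis and hypoxia genes and of unfolded protein and integrated stress response genes, and several genes read in the early lesion had no count at all in TUBO, among them the cell cycle inhibitors Cdkn2a and Cdkn2b. In edgeR 1943 genes were higher and 2174 lower in TUBO, 1083 and 1476 of them by at least 2-fold.

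Of 23 genes of G2/M and mitosis 22 were lower in TUBO and 1 was not called (23 lower when adjusted over the list alone, median -2.07, camera adjusted p = 2.12e-19, adjusted p = 0.388 with an estimated correlation). Mki67 stood at 345 ± 63.0 CPM against 2443 ± 435 CPM (-2.82 ± 0.36, adjusted p = 8.15e-04), and the mitotic kinase gene Plk1 changed by -2.47 ± 0.27. Of 24 G1/S and DNA replication genes 20 were lower and 4 not called (23 lower when adjusted over the list alone, median -1.70, camera adjusted p = 9.89e-15, adjusted p = 0.215 with an estimated correlation), with Ccne1, the G1/S cyclin, at -3.35 ± 0.49. In the CDK inhibitor and senescence list 7 of 17 were lower, 2 higher and 8 not called (8 lower and 2 higher when adjusted over the list alone, median -0.86, or -0.74 with genes at their bound, camera adjusted p = 9.06e-04, adjusted p = 0.254 with an estimated correlation). Cdkn2a (chromosome 4, 89274471 to 89294653) had 16.9 and 16.1 CPM in the early lesion and no count in TUBO, at least 151-fold lower, and Cdkn2b (chromosome 4, 89306299 to 89311039) had 16.0 and 12.5 CPM and no count, at least 131-fold lower. Mtap, the neighbouring gene, had 35.0 and 33.2 CPM in the early lesion and 25.6 and 23.04 CPM in TUBO, while Dmrta1, the next gene of the count table on the other side, had 0.985 and 1.03 CPM in the early lesion and no count in TUBO. Both were named after their values were seen. Cdkn1a was higher in TUBO (1.66 ± 0.15, adjusted p = 3.65e-05). Of 15 p53 targets 4 were higher, 1 lower and 10 not called (5 higher and 1 lower when adjusted over the list alone, median 0.25, camera adjusted p = 0.00334, adjusted p = 0.388 with an estimated correlation), with Plk2 at 2.54 ± 0.16. The call of the CDK inhibitor list was lost without early lesion replicate 1 (adjusted p = 0.124), and without early lesion replicate 2 and DCC control replicate 1 together (0.0563), which also ended that of the p53 targets (0.0735).

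Of 17 glycolysis and hypoxia genes 15 were higher in TUBO and 2 not called (15 higher when adjusted over the list alone, median 1.96, camera adjusted p = 5.78e-17, adjusted p = 0.254 with an estimated correlation). Hk2, a hexokinase, stood at 127 ± 18.5 against 8.89 ± 0.983 CPM, and the hypoxia-induced mitophagy gene Bnip3 changed by 4.43 ± 0.56, adjusted p = 0.00223. Of 15 unfolded protein and integrated stress response genes 10 were higher, 1 lower and 4 not called (10 higher and 2 lower when adjusted over the list alone, median 1.49, camera adjusted p = 3.86e-15, adjusted p = 0.142 with an estimated correlation). Asns, asparagine synthetase, changed by 3.55 ± 0.17, adjusted p = 1.19e-06, Chac1 by 4.81 ± 0.31 and Trib3 by 3.41 ± 0.16. Of 18 cholesterol synthesis genes 11 were lower and 7 not called (13 lower when adjusted over the list alone, median -1.05, camera adjusted p = 5.91e-05, adjusted p = 0.581 with an estimated correlation), with Idi1, the isopentenyl diphosphate isomerase, at -2.97 ± 0.40, adjusted p = 0.00146. In the epithelial list 6 of 22 were higher and 16 not called (6 higher and 1 lower when adjusted over the list alone, median 0.32, camera adjusted p = 0.00903, adjusted p = 0.519 with an estimated correlation), with Krt18 at 1.67 ± 0.27.

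Interferon-related genes were split. Of 20 GBP and IRG GTPases 9 were lower in TUBO and 11 not called (12 lower when adjusted over the list alone, median -2.20, or -1.34 with genes at their bound, camera adjusted p = 9.06e-04, adjusted p = 0.388 with an estimated correlation), with Iigp1 at -4.01 ± 0.59. Of 34 antiviral genes 10 were lower, 1 higher (Bst2, 1.04 ± 0.15) and 23 not called (14 lower and 2 higher when adjusted over the list alone, median -1.13, camera adjusted p = 0.00927, adjusted p = 0.903 with an estimated correlation; fry adjusted p = 0.139), with Ifit2 at -4.24 ± 0.55. In MHC class I presentation 8 of 19 were higher, 3 lower and 8 not called (9 higher and 3 lower when adjusted over the list alone, median 0.33, camera adjusted p = 0.00612, adjusted p = 0.621 with an estimated correlation; fry adjusted p = 0.0536). Psmb8 stood at 52.1 ± 6.39 against 1.68 ± 0.529 CPM, and the class II invariant chain Cd74 changed by 6.99 ± 0.53, adjusted p = 1.06e-04. Of 10 MHC class II genes 2 were higher and 8 not called (2 higher when adjusted over the list alone, median -1.97, or 0 with genes at their bound, camera adjusted p = 0.315, adjusted p = 0.932 with an estimated correlation). Among the genes with the largest changes were Prkcdbp (10.54 ± 0.60), Gjb1 (7.46 ± 0.47), Kcnj15 (7.30 ± 0.79) and Tns4 (6.86 ± 0.52) on the higher side. On the lower side were genes with no count in TUBO: Ptprg, a receptor phosphatase (at least 1146-fold lower, chromosome 14, 11553532 to 12242041), the transcription factor Tfap2b (at least 608-fold), Ppp2r2c (at least 343-fold), Tbc1d9 (at least 309.8-fold) and the bicarbonate transporter Slc4a7 (at least 283-fold).

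None of the 11 lists called by camera held with an estimated correlation. Fewer genes were called on each side with any 1 library of these groups left out. Such a fit leaves 1 library in a group, so the drop does not show that the calls rested on that library. Without early lesion replicate 2 and DCC control replicate 1 together there were 793 higher and 1151 lower, and glmTreat called 410 and 762. Of the genes called lower, 465 (21.4%) were under 5 CPM in both groups, and with the floor of 5 CPM the balance turned, to 2100 higher and 1914 lower (52.3% of calls higher, against 47.2%). The share of olfactory and vomeronasal receptor genes with a count was 63.7% in early lesion replicate 2 and at most 1.24% in the other 3 libraries.

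**Figure D3:**
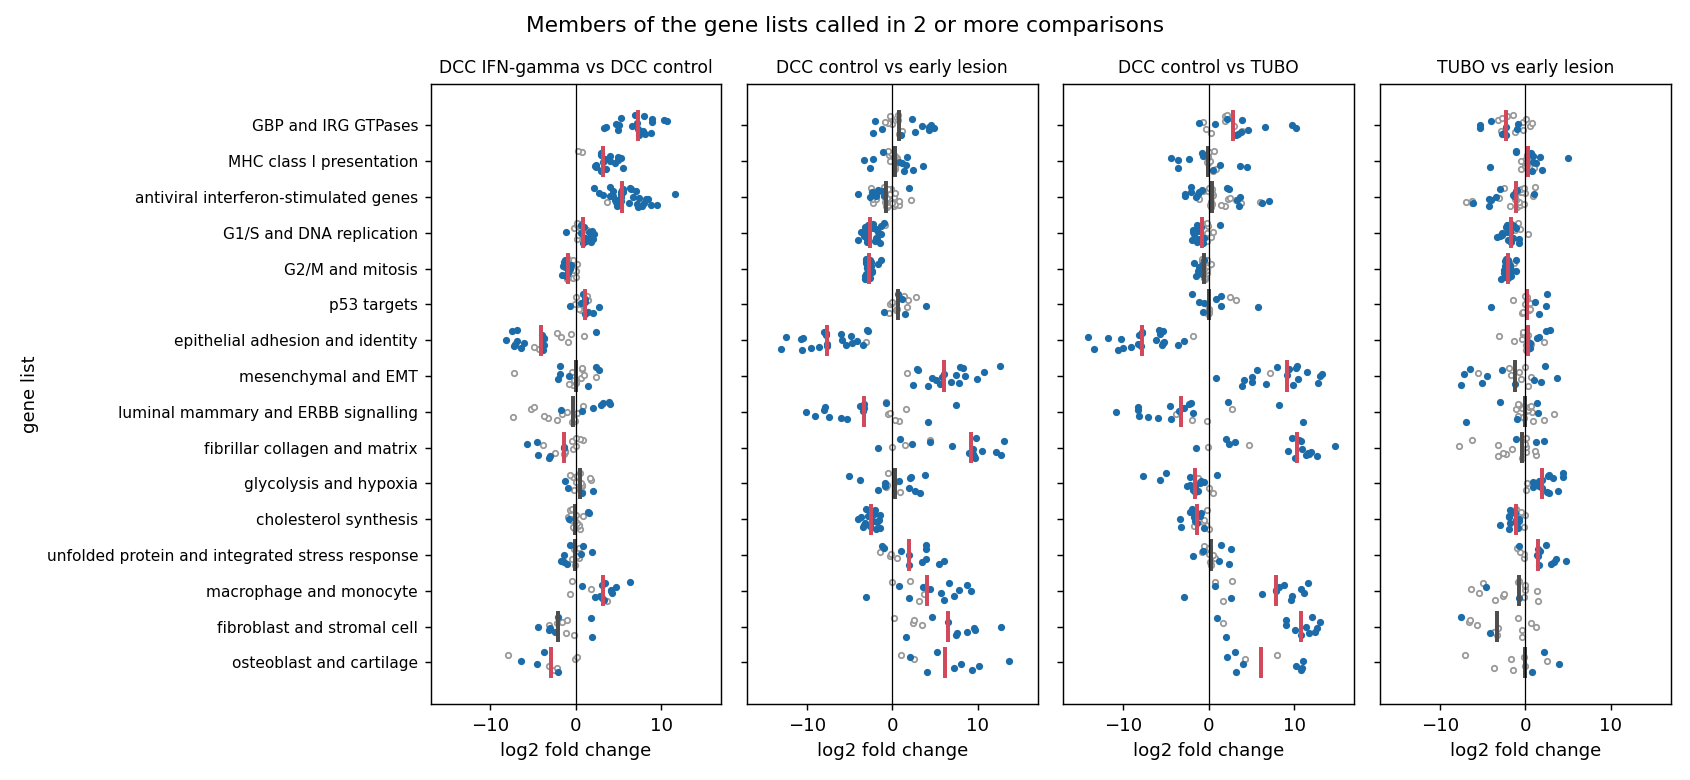
Log2 fold changes of the members of 16 gene lists, those called in at least 2 comparisons, in the 4 comparisons, with filled points for genes with an adjusted p under 0.05, open points for the others, and a vertical bar at each list's median, red where camera called the list. In both comparisons of DCC control the median of the epithelial list lies left of 0, at -7.63 and -7.82, and those of the collagen and mesenchymal lists right of 0.

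**Figure D4:**
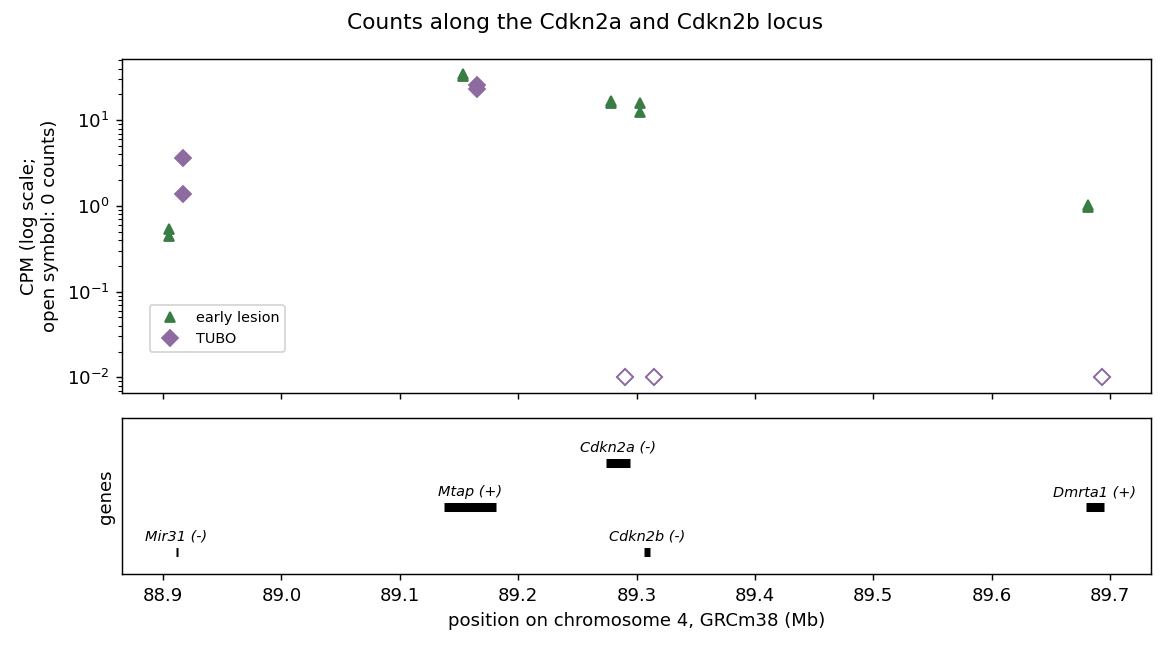
Counts along the part of chromosome 4 around Cdkn2a and Cdkn2b, with CPM on a log scale for the 2 early lesion and 2 TUBO libraries at each gene (top, open symbols for 0 counts) and the gene positions in GRCm38 (bottom, strand in parentheses), for genes that reach 1 CPM in any of these libraries. Mtap was read in both groups, at 25.6 and 23.04 CPM in TUBO, while Cdkn2a, Cdkn2b and Dmrta1 had counts only in the early lesion libraries of these 4.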

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

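The values in this part were chosen after the data were seen. They come from reads that the comparisons do not use, those the table assigns to no single gene, and both libraries of a group lay above both DCC control libraries. Reads on more than 1 gene, as a percent of these and the single-gene reads, came to 1.449% and 1.446% in DCC IFN-gamma replicates 1 and 2 and to 1.156% and 1.265% in TUBO, against 0.958% and 0.911% in DCC control and 0.870% and 0.840% in early lesion. Reads without a unique position came to 15.2% and 20.56% of all reads counted in the deposited table in TUBO. In DCC control they came to 14.2% and 13.7%, in DCC IFN-gamma to 13.9% and 18.0% and in early lesion to 10.99% and 12.7%. DCC IFN-gamma replicate 2 thus lay above TUBO replicate 1.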

How the results depend on the processing

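Apart from the alternatives said in the methods to be chosen after seeing the data, all settings here were fixed before the data were examined. Under RLE and upper quartile factors, no filter, the stricter filter and the floor of 5 CPM, the gene counts of all 4 comparisons and of the overlap stayed within 1.5 times their main values. The cause was not tested for any change in this part unless it is named. In a fit of the 2 groups alone 47.7% of the genes called for interferon-gamma were higher, against 58.8%. GlmTreat asks for more than 2-fold and so called fewer: 570 higher and 327 lower for interferon-gamma, 1486 and 1594 for DCC control against early lesion, 1990 and 1544 for DCC control against TUBO, 410 and 762 for TUBO against early lesion, and 2250 on the same side of both. DESeq2 called 2272 genes lower for interferon-gamma. Without DCC control replicate 1 and early lesion replicate 2 there were 1017 higher and 637 lower for interferon-gamma, 2054 and 2058 for DCC control against early lesion, and 793 and 1151 for TUBO against early lesion. With 1 library left out the counts ranged from 1193 (DCC control replicate 1) to 2500 (DCC IFN-gamma replicate 2) higher and 827 to 1628 lower for interferon-gamma, and for TUBO against early lesion from 1036 (early lesion replicate 2) to 1218 (TUBO replicate 1) higher and 1278 (TUBO replicate 2) to 1900 lower. The lone library of such a group is assumed to vary like the other groups.

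With an estimated correlation camera called 4 lists for interferon-gamma and 0, 0 and 0 in the other comparisons (DCC control against early lesion, DCC control against TUBO, TUBO against early lesion), against 17, 12, 12 and 11. Fry for 1 direction called 24 lists for DCC control against early lesion and 22 against TUBO, and fry for either direction 33, 36, 38 and 33 in the 4 comparisons. The median of no called list changed sign between TMM, RLE, upper quartile and DESeq2 scaling.

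Some named genes that were not called changed sign. Ifngr1 in DCC control against early lesion was at 0.0307 with upper quartile factors, at 0.1114 without both libraries with the most reads outside genes, and between -0.2082 and 0.1182 with 1 library left out. Ifngr2 in DCC control against TUBO was at 0.0058 with upper quartile factors and between -0.2146 and 0.0676 with 1 library left out. In the same comparison Cd274 lay between -0.1281 and 2.2808, or at -0.1268 without both libraries. In TUBO against early lesion Erbb2 lay between -0.0791 and 0.0985, Irf1 between -0.0599 and 0.3169, and Cd274 between -0.5025 and 3.2863, with -0.0616 without early lesion replicate 1. Of the other named genes, RLE factors ended 2 calls, upper quartile factors 5, DESeq2 11, the stricter filter 3, the replicate block 27, the fit of the 2 groups alone 35 and glmTreat 125. Leaving out 1 library ended between 16 and 74 calls, and leaving out both libraries with the most reads outside genes 81. With 1 library left out only the comparisons that use it were followed, so these counts have unlike bases.

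Nothing in the labels ties libraries of the same replicate number. The deviations of same-numbered libraries correlated at 0.140 between the DCC groups and between -0.101 and 0.0701 for the other pairs of groups. These values do not settle whether the DCC replicates were paired. With a replicate block 2061 genes were higher and 1420 lower for interferon-gamma, 3165 and 3151 for DCC control against early lesion, 3508 and 3335 against TUBO, 1907 and 2106 for TUBO against early lesion, and 4457 on the same side of both, with 18, 13, 12 and 13 lists called. Depth limits genes under the floor of 3 counts per library, 0.0953 to 0.183 CPM. The simulated test called 41% to 44% of 2-fold changes, and depth, replicate number and spread between replicates were not separated as causes.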

Other observations

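The tests of explanations in this part were all chosen after the result was seen, while the gene lists were fixed before. Some lists were not called by camera in the comparisons given beside them. Of 15 dormancy-associated genes 6 were higher and 3 lower in DCC control than in both early lesion and TUBO, with a median log2 fold change of 0.90 against early lesion (camera adjusted p = 0.206, 8 higher and 3 lower when adjusted over the list alone). After interferon-gamma 4 rose, 4 fell and 7 were not called, with a median of -0.27 and a mean of 0.12 (camera adjusted p = 0.643, 5 higher and 4 lower when adjusted over the list alone). Of 20 genes of migration, bone homing and proteolysis 8 were higher and 4 lower than in both (camera adjusted p = 0.0525 against early lesion, 0.122 against TUBO). Spp1 (osteopontin), a gene named after its values were seen, stood at 13477 and 18834 CPM in DCC control, 9921 and 24886 CPM in DCC IFN-gamma, 4399 and 3539.8 CPM in early lesion and 3339.5 and 3807 CPM in TUBO. Of 12 basal and myoepithelial genes 4 were higher and 3 lower than in both, with a median of 1.85, a mean of 0.68 and a camera test on the lower side against early lesion (camera adjusted p = 0.475). Of 10 MHC class II genes 5 were higher in DCC control than in both (camera adjusted p = 0.0525 against early lesion, 0.397 against TUBO). Xist, the RNA of the inactive X chromosome and also chosen after its values were seen, had 2576 and 2626 CPM in DCC control, 1282 and 1842 CPM in DCC IFN-gamma, 2855 and 2566 CPM in early lesion and 1.07 and 3.58 CPM in TUBO.

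Macrophage markers were higher in the treated DCC libraries. The median of the list was 3.17 with TMM and 2.98 with upper quartile factors, against -0.20 and -0.40 for all genes. The list thus stood above the other genes under both. A change of factors moves all genes together and could not have removed a rise of this size, so it is no test of scaling as the cause. Of 16 markers 12 rose, among them Csf1r (from 18.5 and 16.9 to 193 and 147 CPM), Laptm5 (from 14.7 and 16.1 to 169.8 and 156 CPM) and Lyz2 (from 18.7 and 20.6 to 161 and 105 CPM). A larger share of macrophages in the treated cultures could raise most markers, the abundant ones by similar factors. The factors of Csf1r, Laptm5, Lyz2 and Cd68 (from 19.1 and 17.1 to 163 and 138 CPM) lay near each other. They were not alike over all markers, since C1qa went from 8.95 and 12.5 to 238 and 168 CPM. C1qb went from 13.4 and 14.5 to 282 and 194 CPM. Mrc1 (from 8.77 and 7.68 to 5.39 and 4.96 CPM) and Cx3cr1 were not called. The log2 changes of the markers had an SD of 1.86. Induction of these genes by interferon-gamma without more macrophages allows such a spread and stays open. Similar factors were expected from a larger share alone, so the count of markers that rose does not settle it either.

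The DCC libraries held few epithelial and many osteoblast and stromal transcripts. Over 22 epithelial genes the DCC control level was 0.550% of the early lesion level at the median, from 0.0097% to 14.3% with 14 genes under 2%, which argues against carcinoma cells like those of the early lesion as a main part of these libraries. Osteoblast or stromal lineage cells of the marrow may contribute, with 8 of 10 osteoblast markers higher than in both other groups. Carcinoma cells in a mesenchymal state stay open, with Erbb2 at 9.22% of its early lesion level. Whether reads of a rat neuT transgene were counted on mouse Erbb2 is not known here. This level therefore does not show whether the cells carried the transgene. The labels name the cells as disseminated cancer cells.

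Of 9960 genes with at least 3 CPM in both early lesion libraries 88 had no count in either TUBO library, and 58 of them were read at that level in DCC control. At the early lesion level a median of 409.5 counts would have been read in TUBO (185.6 at the lowest). The floor of 3 CPM made counts of this size certain, so they are no separate test of too few reads. Neighbours were taken among the 9960 genes alone, in order of position. They made up 4 pairs at 0, against a median of 1 and a highest value of 4 in 1000 shuffles of positions (one-sided permutation p = 0.006). A first criterion, more pairs than in every shuffle, was not met. The permutation p was taken as criterion only after this result was seen. It therefore cannot decide the question, and positions by chance stay open. The pairs were Susd4 and Disp1 (chromosome 1, 182763860 to 183221522), Sox12 and Zcchc3 (chromosome 2, 152393611 to 152415027), Cdkn2a and Cdkn2b (chromosome 4, 89274471 to 89311039), and Evc and Evc2 (chromosome 5, 37289098 to 37425055). The interval of Susd4 and Disp1 holds 3 genes of the count table, none with a count in TUBO. Lost segments of DNA in TUBO and silencing of neighbouring genes both stay open, since no test here tells them apart.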
